A study of Mus musculus with 15 samples.

How the data were processed

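Brown adipose tissue, the heat-producing fat depot of mice, was profiled by bulk RNA sequencing in animals given bisphenol S (BPS) or vehicle. Bisphenol S is an industrial replacement for bisphenol A. The labels gave 8 vehicle and 7 BPS samples, named here by group and by the replicate number in their titles. Dose, duration, age, sex and strain were not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads, and libraries were made with random-primed cDNA and sequenced by a service laboratory. Strandedness was not given in the sources used here, so overlapping and antisense genes cannot be separated.

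The deposited values were FPKM, a measure of abundance scaled by transcript length and by the total of the library, given by the authors to 2 decimals. Per the submitters' processing notes, the tools included HISAT2 2.1.0, Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5, with the genome build GRCm38.p6. The authors' deposited table also held a log2 ratio of BPS to vehicle, a p-value and a q-value for each gene, and group averages. Those columns were used here only where they are named. FPKM divides by the total of each library, so a rise of abundant transcripts lowers the values of all others. Genes with near-identical copies (Hspa1a and Hspa1b, Hba-a1 and Hba-a2, Xlr3a and Xlr3b, and the Cyp2b and interferon-inducible GTPase families) share reads that RSEM divides by estimate, so their individual values are uncertain.

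The table held 16774 genes with Entrez identifiers and symbols. Of these identifiers, 16727 matched a RefSeq gene table of the same build, which gave the coordinates, and 16500 had an identical symbol there. The design had assumed counts as the main case and named a limma test for normalized values. Because the file held FPKM, that test was used: limma 3.58.1 in R 4.3.3, with an intensity trend and robust spread, on log2(FPKM + 1). Genes with at least 1 FPKM in at least 7 libraries were tested, 12156 in all, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. Errors of log2 changes are limma standard errors, and errors of FPKM are SDs.

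A total of 40 gene lists with 964 entries were fixed before the data were examined. Of these entries, 926 matched a gene of the table, 2 of them under another symbol. The 13 genes of one of these lists, the mitochondrially encoded genes, had no match and are not analysed here. Lists with at least 5 tested members, 38 in all, were tested with camera, which asks whether a list moved relative to all other genes, with a preset correlation between genes of 0.01 and again with an estimated correlation. For 13 lists of markers of other cell types, the mean of log2(FPKM + 1) over the members was compared between groups with a two-sided exact permutation test over all 6435 splits, for which the smallest possible p is 0.000155. Named genes were fixed by a rule before the data were examined: the 10 largest rises and falls past the threshold, with a mean of at least 1 FPKM in the higher group and without predicted or unnamed gene models, topped up with 5 genes of smallest p where fewer than 10 passed; up to 4 members of smallest p of each list, and all 4 where the list passed; and 13 genes named in advance. Some genes that the rule names are not reported here; they stayed in every fit, list and count of calls. Any other gene is said to have been chosen after its values were seen.

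The steps were tested on simulated data with log2 changes added to the real means and spreads of 12156 genes. Each gene was drawn independently from a normal distribution with the same spread in both groups. Only genes with a mean log2 value over 2 were changed. Correlation between genes and unequal spreads of the groups were not simulated, so the shares below may not hold for the real data. For 8 against 7 libraries, 53.7% of genes changed by 0.5, 83.6% of those changed by 1 and 98.5% of those changed by 2 were recovered, with 8 false calls among 165. For 8 against 3 libraries the shares were 34.3%, 73.1% and 95.5%, with 9 false calls among 144.

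No counts were used, so the absolute depth of the libraries is unknown. In the low values, the most frequent ratio between each library and vehicle replicate 1 lay between -0.38 and 0.13 on the log2 scale, with 3.99% to 10.3% of the compared genes in that bin. The lowest, -0.38, was that of BPS replicate 4, where the peak held 3.99% of genes. The highest correlation of any pair of libraries was 0.994.

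Alternative settings were quantile normalization, median scaling, no trend, non-robust spread, no filter, a stricter filter of 5 FPKM, pseudocounts of 0.1 and 5, a term for the replicate number, the skeletal muscle score as a covariate, and each library left out in turn. The median over members and standardized members were tried for the cell type scores. Alternatives that need counts did not apply, and that with a surrogate variable was not run. A further 4 alternatives were chosen after seeing the data: without BPS replicates 4, 5, 6 and 8, the Y-linked transcript level as a covariate, without vehicle replicates 2, 6 and 8, and the first of these with the muscle score. BPS replicates 4, 5, 6 and 8 are the libraries whose Y-linked level lay below that of every vehicle library. Vehicle replicates 2, 6 and 8 are those with the highest skeletal muscle scores.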

Results

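Transcript levels in brown adipose tissue were measured in 8 vehicle-treated and 7 BPS-treated mice, a comparison that asks, per the title of the series, how an environmental dose of BPS affects this tissue in relation to aging. FPKM summed to between 756556 in BPS replicate 4 and 920855 in vehicle replicate 7, and between 11527 and 12306 genes reached 1 FPKM in each library. The 10 most abundant genes held 11.3% to 15.4% of each sum, the most in BPS replicate 4. The labels give each sample its own mouse identifier, and the p-values measure the spread between libraries. That is the spread between mice only if each library holds RNA of its own mouse alone. For some BPS libraries, described below, this is in doubt, and they may not count as independent mice. The depth in reads is unknown, since no counts were used.

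Of the BPS libraries, 4 stood apart from the remaining 11 in transcripts of the sex chromosomes. The mean level of the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d, relative to the vehicle mean, was 0.437% in BPS replicate 4, 26.4% in BPS replicate 8, 53.5% in BPS replicate 5 and 74.5% in BPS replicate 6. In the vehicle libraries it ranged from 82.9% to 114.7%, and BPS replicates 1, 2 and 3 lay at 96.9%, 102.2% and 92.0%. Kdm6a, an X-linked gene that escapes X inactivation, was at 4.54 ± 0.491 FPKM in vehicle (SD, n = 8) and at 9.92, 7.49, 6.83 and 7.95 FPKM in BPS replicates 4, 5, 6 and 8. The pseudogene transcript H2-Ea-ps, chosen after its values were seen, was listed at 0 in the 11 other libraries and at 12.96, 9.92, 4 and 15.32 FPKM in these 4. Counts that lead the comparisons below are therefore given with all 15 libraries and without these 4.

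**Figure D1:**
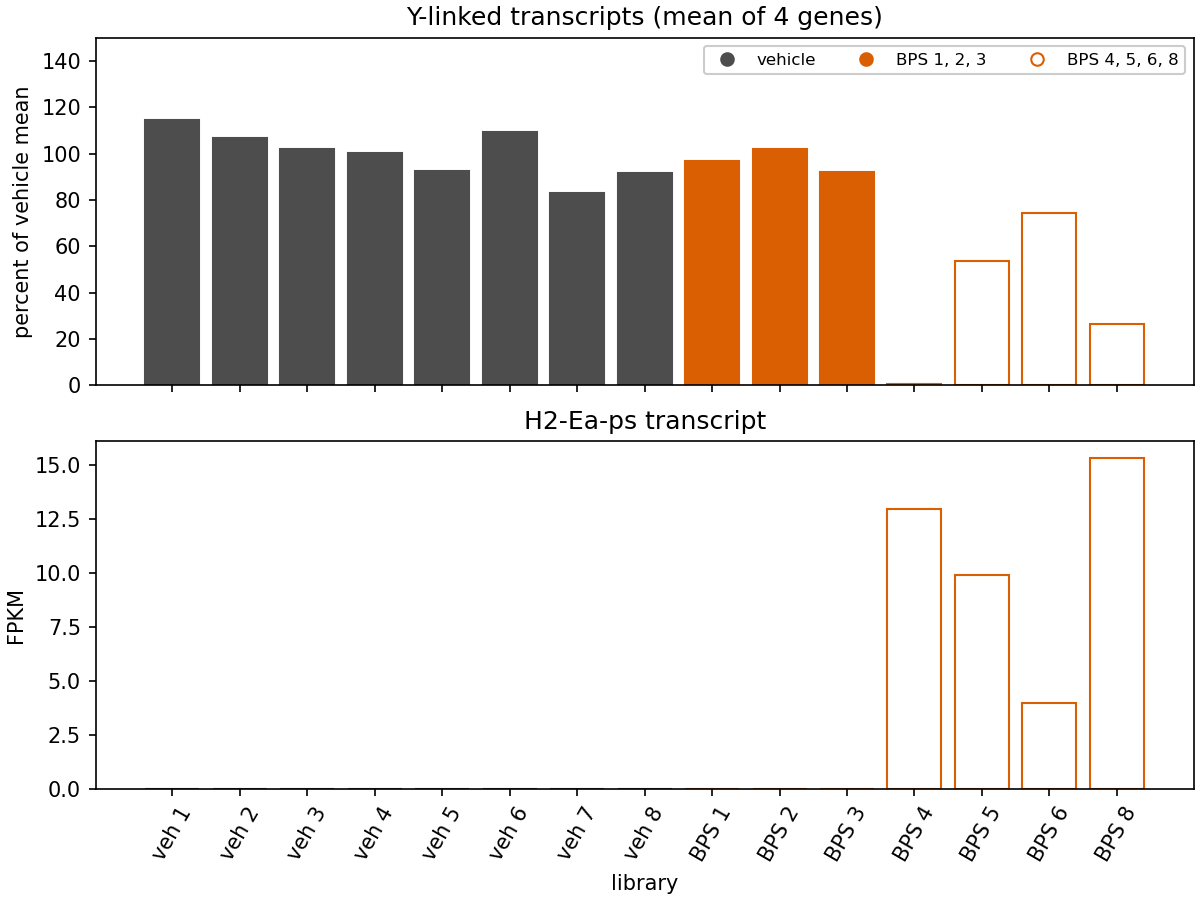
Bars show, per library, the mean of the Y-linked genes as a percent of the vehicle mean (upper panel) and H2-Ea-ps in FPKM (lower panel). Open bars mark BPS replicates 4, 5, 6 and 8, which have 0.437% to 74.5% of the vehicle Y-linked level and 4 to 15.32 FPKM of H2-Ea-ps, while that transcript is listed at 0 elsewhere.

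Across all 15 libraries, 42 genes were higher and 8 lower in BPS at an adjusted p under 0.05 (limma, Benjamini-Hochberg), out of 12156 tested. The genes with the largest rises included the xenobiotic-metabolizing enzymes Cyp2b10, Cyp4b1 and Fmo2, the secreted proteins Hp (haptoglobin), C3 (complement component 3) and Igfbp3, and the purine-degrading enzyme Xdh. The largest falls were those of the heat shock gene Hspa1a, the immediate-early gene Nr4a3 and the X-linked Xlr3b. Groups did not overlap in 34 of these 50 genes, which the choice of called genes favours. Among all 12156 tested genes they did not overlap in 70, where a random division of independent libraries gives 0.0311%. For some BPS libraries that independence is in doubt. In the authors' deposited table, 530 genes were higher and 431 lower at a q under 0.05, and 49 of the 50 genes were among them.

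Cyp2b10 (Entrez 13088, chromosome 7, 25897658 to 25926624, GRCm38.p6) rose from 7.69 ± 3.73 FPKM in vehicle (SD, n = 8) to 29.7 ± 14.4 FPKM in BPS (SD, n = 7). Its log2 change was 1.77 ± 0.323 (SE), with an adjusted p of 0.04. Hp (Entrez 15439, chromosome 8, 109575128 to 109579172) rose from 772 ± 221 to 2525 ± 1101 FPKM, a log2 change of 1.67 ± 0.237 with an adjusted p of 0.0185. C3 (Entrez 12266, chromosome 17, 57203967 to 57228136) rose from 139.5 ± 35.2 to 304.8 ± 84.8 FPKM, a log2 change of 1.11 ± 0.183 with an adjusted p of 0.032. Xdh (Entrez 22436, chromosome 17, 73883895 to 73950397) rose from 50.7 ± 16.1 to 108.6 ± 21.7 FPKM, a log2 change of 1.12 ± 0.183 with an adjusted p of 0.032. Cyp4b1 (Entrez 13120, chromosome 4, 115624698 to 115647721) rose from 40.2 ± 9.62 to 98.3 ± 34.7 FPKM, a log2 change of 1.24 ± 0.192 with an adjusted p of 0.0264. All 7 BPS libraries lay above the vehicle mean for each of these 5 genes, which the choice of called genes favours. Above every vehicle library lay 7 BPS libraries for Hp and Cyp4b1, and 6 for Cyp2b10, C3 and Xdh.

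Igfbp3 (Entrez 16009, chromosome 11, 7206086 to 7215498), an insulin-like growth factor binding protein, rose from 15.9 ± 4.03 to 62.7 ± 41.3 FPKM, with a log2 change of 1.68 ± 0.341 and an adjusted p of 0.0478. Its level was 28.0 ± 5.44 FPKM in BPS replicates 1, 2 and 3 (SD, n = 3), and without the 4 other libraries its log2 change was 0.80 ± 0.222 with an adjusted p of 0.299. Other rises were also measured with and without these libraries. With all of them, log2 changes were 1.42 ± 0.293 for Cd164l2, 1.33 ± 0.275 for Fmo2, 1.33 ± 0.259 for Wfdc17 and 1.26 ± 0.224 for Hpd, an enzyme of tyrosine breakdown. With the 4 left out these values were 0.71 ± 0.241, 0.60 ± 0.165, 0.63 ± 0.179 and 0.79 ± 0.185, with adjusted p between 0.176 and 0.433. Under the same setting Hp, Cyp4b1 and Xdh had log2 changes of 1.42 ± 0.261, 1.00 ± 0.193 and 1.22 ± 0.247, with adjusted p of 0.0523, 0.0665 and 0.0877. Over 29 alternatives the adjusted p of Hp ranged from 0.0101 to 0.325, that of Cyp4b1 from 0.0186 to 0.325, that of Xdh from 0.0196 to 0.325 and that of Igfbp3 from 0.0375 to 0.362.

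Among the 8 lower genes, Xlr3b (Entrez 574437, chromosome X, 73192150 to 73202930) had the smallest p. It fell from 18.3 ± 1.72 FPKM in vehicle to 8.22 ± 2.45 FPKM in BPS, a log2 change of -1.11 ± 0.142 with an adjusted p of 0.0106, and all 7 BPS libraries lay below every vehicle library. Hspa1a (Entrez 193740, chromosome 17, 34969359 to 34972156), an inducible HSP70 chaperone, fell from 30.4 ± 27.8 to 3.81 ± 2.28 FPKM, a log2 change of -2.43 ± 0.449 with an adjusted p of 0.0449. Nr4a3 (Entrez 18124, chromosome 4, 48045078 to 48086447), an orphan nuclear receptor, fell from 7.63 ± 6.20 to 1.49 ± 0.981 FPKM, a log2 change of -1.68 ± 0.333 with an adjusted p of 0.0473. Smaller falls included -0.52 ± 0.107 for Chac2, -0.48 ± 0.0986 for Angptl6, -0.36 ± 0.0727 for Ube2s and -0.30 ± 0.0544 for Cacybp. In the fit without the 4 libraries Hspa1a and Nr4a3 had log2 changes of -1.83 ± 0.644 and -1.11 ± 0.418, with adjusted p of 0.485 and 0.507, and over all alternatives their adjusted p ranged from 0.0316 to 0.485 and from 0.0352 to 0.534. The genes of next smallest p in this direction missed the threshold with an adjusted p of 0.0627: Pdcl3 (-0.34 ± 0.0747), Bhlhe40 (-1.16 ± 0.257), H2c8 (-0.70 ± 0.157), Tceal1 (-0.50 ± 0.112) and Xlr3a (-0.92 ± 0.206).

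Without BPS replicates 4, 5, 6 and 8, 32 genes were higher and 1 lower, and 5 genes passed the threshold in both fits. These 5 were Cyp2b10, C3, Etfbkmt, Card6 and Xlr3b. In the fit of 11 libraries Cyp2b10 had a log2 change of 2.11 ± 0.36 with an adjusted p of 0.0432, C3 one of 1.295 ± 0.229 (adjusted p 0.0434) and Xlr3b one of -0.76 ± 0.102 (adjusted p 0.00794). Etfbkmt (Entrez 320204, chromosome 6, 149141476 to 149151171), a mitochondrial lysine methyltransferase, was at 34.0 ± 2.91 FPKM in vehicle and 48.9 ± 5.24 FPKM in all BPS libraries, with log2 changes of 0.51 ± 0.0756 and 0.56 ± 0.1 in the fits of 15 and 11 libraries. Card6 (Entrez 239319, chromosome 15, 5096920 to 5116562) was at 1.95 ± 0.203 and 2.88 ± 0.435 FPKM, with log2 changes of 0.39 ± 0.0795 and 0.54 ± 0.0952. Etfbkmt and Card6 were named after their values were seen. Over 29 alternatives the adjusted p of Cyp2b10 ranged from 0.0197 to 0.329, that of C3 from 0.0194 to 0.325 and that of Xlr3b from 0.00284 to 0.325. Xlr3b passed in 27 of them and missed with the Y-linked level as a covariate and without vehicle replicates 2, 6 and 8.

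**Figure D2:**
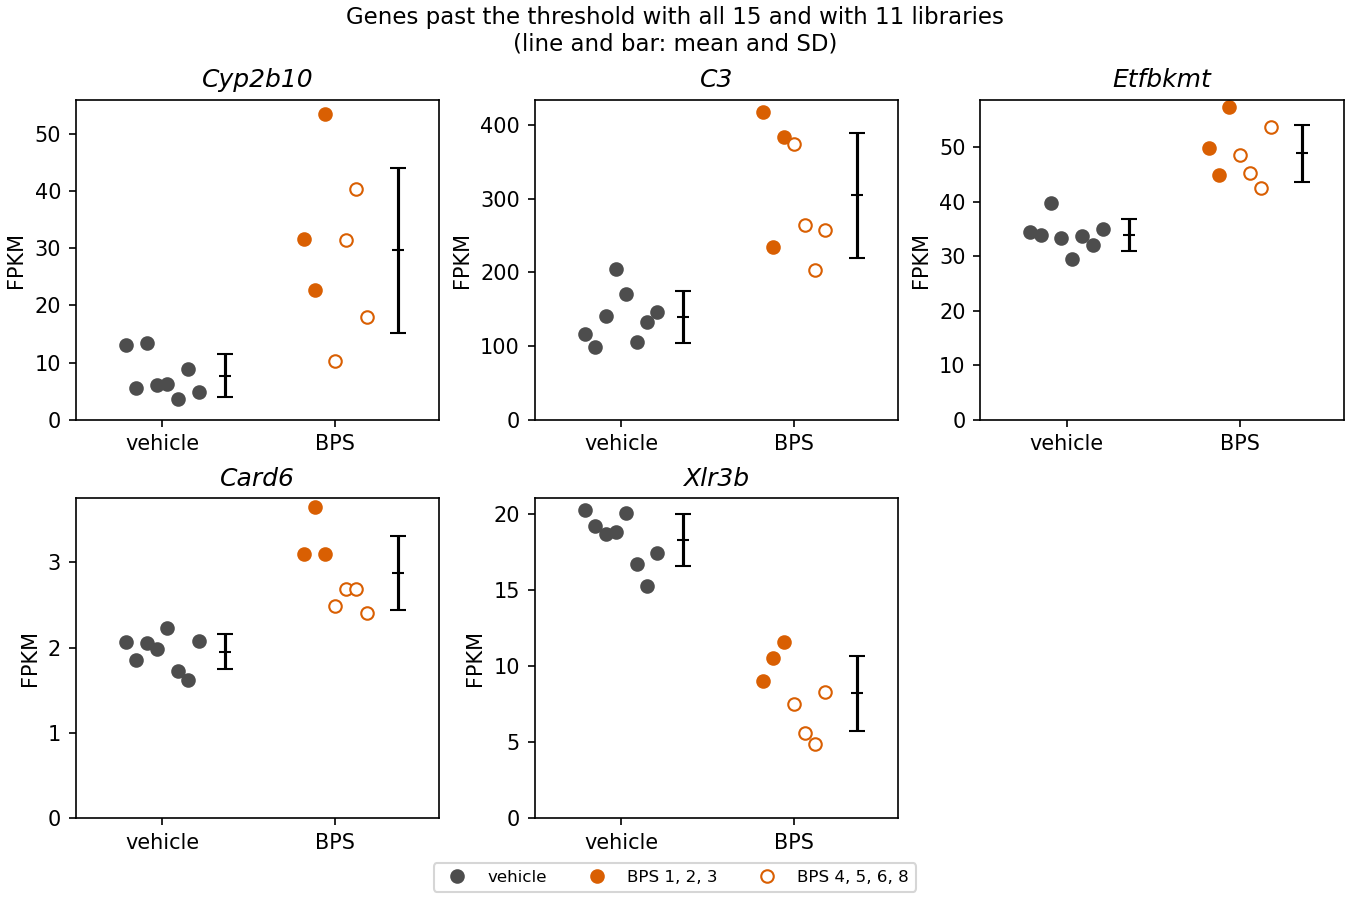
Points are FPKM of single libraries for the 5 genes past the threshold in both fits, with the mean and SD of each group beside them. Open points are BPS replicates 4, 5, 6 and 8. Vehicle means are 7.69 FPKM for Cyp2b10, 139.5 for C3, 34.0 for Etfbkmt, 1.95 for Card6 and 18.3 for Xlr3b, against BPS means of 29.7, 304.8, 48.9, 2.88 and 8.22.

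The counts depended on single libraries. No gene was higher and 1 lower without vehicle replicate 8 or BPS replicate 8, and 1 was higher and 1 lower without vehicle replicate 2, 6 or 7. Without BPS replicate 3 or 5 the counts were 2 higher and 1 lower, without BPS replicate 4 they were 3 and 1, without BPS replicate 6 they were 9 and 1, without vehicle replicate 3 they were 12 and 1, and without vehicle replicate 5 they were 9 and 3. Without BPS replicate 2 they were 61 and 27, without vehicle replicate 1 they were 31 and 5, and without BPS replicate 1 they were 30 and 3. Xlr3b passed in each of these fits. The changes of the 50 genes moved less than the counts. With each library left out, their median ratio to the changes with all libraries lay between 0.921 and 1.05. The 50 genes were chosen with these same libraries, which favours a ratio near 1. With the skeletal muscle score as a covariate, 1 gene was higher and 1 lower, and with the Y-linked level as a covariate no gene passed (limma; 970 genes at an unadjusted p under 0.05, against 2803 without covariates).

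Genes of lipid handling in fat cells rose as a list. Of 23 tested genes of lipid uptake, droplets and lipolysis, 18 had positive changes, with a median log2 change of 0.35 and an adjusted p of 0.0104 (camera; adjusted p = 0.724 with an estimated correlation). None passed over all genes, and 5 were higher when adjusted over the list alone. The fatty acid carrier Cd36 was at 962 ± 226 FPKM in vehicle and 1456 ± 214 FPKM in BPS (log2 change 0.62 ± 0.156, adjusted p 0.0812). The droplet protein gene Cidec was at 525 ± 149 and 865 ± 231 FPKM (0.74 ± 0.2, adjusted p 0.093), the lipolysis inhibitor G0s2 at 360 ± 100.4 and 568 ± 122 FPKM (0.68 ± 0.191, adjusted p 0.0955) and the triglyceride lipase Pnpla2 at 827 ± 234 and 1249 ± 207 FPKM (0.63 ± 0.183, adjusted p 0.102). The list kept its direction without the 4 libraries, with a median of 0.20 and an adjusted p of 0.03 (adjusted p = 0.911 with an estimated correlation). With the muscle score as a covariate its median was 0.22 with an adjusted p of 0.0729, and without vehicle replicates 2, 6 and 8 it was 0.15 with an adjusted p of 0.203. With the Y-linked level as a covariate the median was 0.15 with an adjusted p of 0.046. Over 29 alternatives the adjusted p ranged from 0.000454 to 0.203.

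Cytosolic ribosomal protein genes were also higher, with positive changes in 38 of 44 members, a median of 0.10 and an adjusted p of 0.0065 (adjusted p = 0.835 with an estimated correlation). No member passed over all genes or adjusted over the list alone. Rpl3 had a log2 change of 0.40 ± 0.115, Rpl5 one of 0.25 ± 0.0809 and Rpl6 one of 0.21 ± 0.0714, with adjusted p between 0.0969 and 0.121. The median was 0.06 under median scaling (adjusted p 0.032) and 0.17 under quantile normalization (adjusted p 4.88e-06). With single libraries left out, the list missed the threshold without vehicle replicate 5 (median 0.07, adjusted p 0.0645), BPS replicate 2 (0.0519) or BPS replicate 3 (0.101), and had an adjusted p of 2.96e-09 without the 4 libraries (median 0.17; adjusted p = 0.911 with an estimated correlation), within a range of 3.51e-13 to 0.101 over 29 alternatives.

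Thermogenic and respiratory genes were lower as lists, and their direction turned without the 4 libraries. The 27 tested brown adipocyte thermogenic genes had a median log2 change of -0.29 and an adjusted p of 0.00384 (adjusted p = 0.724 with an estimated correlation), with 22 negative members and none past the threshold over all genes or adjusted over the list alone. The members of smallest p were Esrrg (-0.52 ± 0.163), S100b (-0.94 ± 0.333), Ppargc1a (-0.28 ± 0.142) and Cox7a1 (-0.86 ± 0.443), with adjusted p of 0.11, 0.134, 0.248 and 0.258. Of 75 nuclear-encoded respiratory chain subunits, 68 had negative changes, with a median of -0.24 and an adjusted p of 1.45e-08 (adjusted p = 0.724 with an estimated correlation), and none passed alone by either adjustment. Among these, Cox7c was at 5770 ± 838 FPKM in vehicle and 4466 ± 1124 FPKM in BPS (-0.41 ± 0.177), Cox5a at 3165 ± 531 and 2283 ± 865 FPKM (-0.58 ± 0.25), Ndufa5 at 1234 ± 162 and 929 ± 357 FPKM (-0.51 ± 0.228) and Atp5l at 5160 ± 759 and 4164 ± 895 FPKM (-0.33 ± 0.153), with adjusted p between 0.189 and 0.212. Without these libraries the medians of the lists were 0.16 (adjusted p 0.341) and 0.09 (adjusted p 0.0599). Without BPS replicate 4 alone the log2 changes were -0.62 for S100b, -0.39 for Cox7a1, -0.25 for Cox7c, -0.34 for Cox5a, -0.30 for Ndufa5 and -0.21 for Atp5l, and without all 4 libraries they were -0.48, -0.10, -0.11, -0.06, 0.02 and -0.07. In the first of these fits the thermogenic list had a median of -0.09 and an adjusted p of 0.069, and the respiratory list a median of -0.09 and an adjusted p of 0.000388. Under quantile normalization the respiratory median was -0.14 (adjusted p 2.21e-05), with Cox7c at -0.13 and Atp5l at -0.08, and without vehicle replicates 2, 6 and 8 the thermogenic median was -0.49 (adjusted p 4.6e-05). White adipocyte markers had a median of 0.64 with all libraries, with 10 of 12 tested members positive, and of -0.305 without the 4 libraries, and missed the threshold in both fits (adjusted p 0.113 and 0.0663). Their score over 13 members was 5.95, 5.33, 5.14 and 5.67 in BPS replicates 4, 5, 6 and 8 (log2 FPKM), above the highest vehicle library at 5.05, and its group difference of 0.60 had an exact permutation p of 0.138, or 0.317 after adjustment. Over 29 alternatives adjusted p ranged from 4.6e-05 to 0.94 for the thermogenic and from 9.01e-15 to 0.647 for the respiratory list.

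Single thermogenic regulators did not differ beyond the spread between libraries. Ucp1 (chromosome 8, 83290348 to 83298456), the uncoupling protein that makes brown fat produce heat, was at 1043 ± 708 FPKM in vehicle (SD, n = 8) and 1096 ± 600.2 FPKM in BPS (SD, n = 7), a log2 change of -0.08 ± 0.61 with an adjusted p of 0.947. It stood at 82.3 FPKM in BPS replicate 4 and at 578 to 1960 FPKM in the other BPS libraries. Log2 changes were -0.28 ± 0.457 for Cidea, -0.52 ± 0.365 for Dio2, which activates thyroid hormone, 0.06 ± 0.104 for Prdm16 and -0.17 ± 0.255 for Adrb3, with adjusted p between 0.387 and 0.731. Esr1, an estrogen receptor, had a log2 change of 0.25 ± 0.142 (adjusted p 0.297). Lep, the leptin gene of white fat, was at 29.9 ± 12.6 FPKM in vehicle and 112.8 ± 95.03 FPKM in BPS (1.38 ± 0.559, adjusted p 0.17), and at 27.4 ± 14.6 FPKM in BPS replicates 1, 2 and 3. Acta1, skeletal muscle actin, was at 2566 ± 3525 and 354 ± 462 FPKM (-2.43 ± 1.61, adjusted p 0.363).

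**Figure D3:**
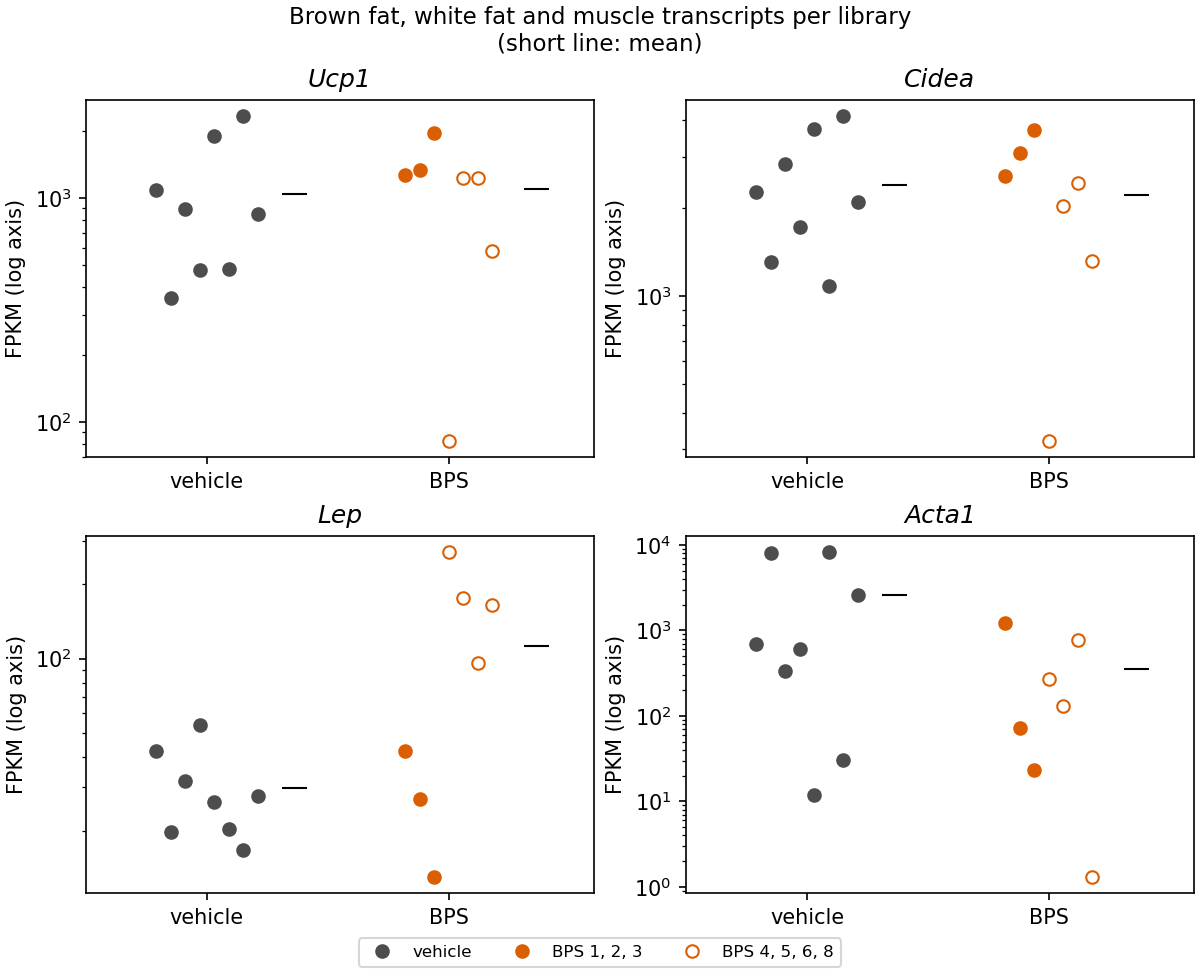
Points are FPKM of single libraries on a log axis for Ucp1, Cidea, Lep and Acta1, and the short lines are group means. Open points are BPS replicates 4, 5, 6 and 8. BPS replicate 4 has 82.3 FPKM of Ucp1, 320 of Cidea and 271 of Lep, against vehicle means of 1043, 2399 and 29.9 FPKM.

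The creatine and calcium cycling list was lower, with a median of -0.59 over 11 tested genes and an adjusted p of 0.0104 (adjusted p = 0.724 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. The members of smallest p were the creatine transporter gene Slc6a8 (-0.60 ± 0.198), Alpl (-0.59 ± 0.248), Gatm (-0.60 ± 0.266) and Atp2a2 (-0.62 ± 0.406), with adjusted p between 0.119 and 0.356. Skeletal muscle also expresses Atp2a2. Without vehicle replicate 2 the median was -0.36 with an adjusted p of 0.0171. With the muscle score as a covariate the median was -0.21 with an adjusted p of 0.143, and without the 4 libraries it was -0.02 with an adjusted p of 0.637. With a pseudocount of 5 it was -0.38 (adjusted p 0.0103). Without the filter on low values it was -0.18 (adjusted p 0.0707), and without vehicle replicates 2, 6 and 8 it was -0.23 (adjusted p 0.075). Its adjusted p ranged from 0.00543 to 0.949 over 29 alternatives.

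Genes of the aging-related lists gave single calls and no list call. Of 35 tested senescence-associated genes, only Igfbp3 passed over all genes, 2 were higher and 1 lower adjusted over the list alone, and the list had a median of 0.13 and an adjusted p of 0.814. Cdkn1a, which encodes p21, was at 54.9 ± 29.9 FPKM in vehicle and 64.5 ± 21.7 FPKM in BPS (0.32 ± 0.29, adjusted p 0.504). Cdkn2a (0.755 ± 0.592 and 0.676 ± 0.529 FPKM) and Il6 (0.748 ± 1.02 and 0.394 ± 0.324 FPKM) lay below the filter and were not tested. Sirt6, a chromatin deacylase, rose from 3.75 ± 0.78 to 5.77 ± 0.651 FPKM, a log2 change of 0.52 ± 0.104 with an adjusted p of 0.0473, and had an adjusted p of 0.0667 under median scaling and 0.449 without the 4 libraries, within a range of 0.0398 to 0.48 over 29 alternatives. Of the 18 tested sirtuin and NAD genes, 3 were higher adjusted over the list alone, with an adjusted p of 0.718 for the list. The 23 p53 target genes had a median of -0.08 and an adjusted p of 0.232, with Rrm2b at 0.33 ± 0.101.

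Xenobiotic metabolism held 2 of the 42 higher genes, Cyp2b10 and Fmo2, and 3 adjusted over the list alone, while the list of 22 tested genes had a median of 0.14 and an adjusted p of 0.113. Among 19 nuclear and hormone receptors, 1 was higher and 2 lower adjusted over the list alone, the list had a median of 0.15 and an adjusted p of 0.797, and the vitamin D receptor gene Vdr was at 1.39 ± 0.483 and 0.774 ± 0.246 FPKM (-0.42 ± 0.124, adjusted p 0.104).

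Immediate-early and heat shock genes, which respond to handling and stress, were lower with all libraries. The 20 immediate-early genes had a median of -0.40 and an adjusted p of 0.00155, and the 15 heat shock genes a median of -0.30 and an adjusted p of 3.93e-06, each with an adjusted p = 0.724 with an estimated correlation. Nr4a3 and Hspa1a passed over all genes, and 3 and 4 members were lower adjusted over the list alone. Other members were Atf3 (-1.57 ± 0.437), Ier3 (-0.68 ± 0.207), Klf2 (-0.90 ± 0.37), Hspa1b (-1.97 ± 0.471), Hsph1 (-0.82 ± 0.222) and Bag3 (-0.53 ± 0.188), with adjusted p between 0.0789 and 0.17. The immediate-early list was higher without the 4 libraries, with a median of 0.37 and an adjusted p of 0.000436 (adjusted p = 0.911 with an estimated correlation), and 5 members were higher adjusted over the list alone. The heat shock list then had a median of -0.06 and an adjusted p of 0.0532, and with the Y-linked level as a covariate its median was 0.0035 while camera's direction was lower (adjusted p 0.019). Without vehicle replicate 1 the immediate-early list had a median of -0.25 and without BPS replicate 2 one of -0.65, with adjusted p of 0.00632 and 1.18e-05. Over 29 alternatives, either direction included, adjusted p ranged from 1.18e-05 to 0.0461 for immediate-early and from 5.3e-07 to 0.13 for heat shock genes.

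The type I interferon list likewise turned. With all libraries its 28 genes had a median of -0.20 and an adjusted p of 0.0033 (adjusted p = 0.777 with an estimated correlation), with no member past the threshold by either adjustment, and Ifit1, Isg15, Usp18 and Bst2 had log2 changes of -0.69 ± 0.221, -0.63 ± 0.24, -0.64 ± 0.248 and -0.51 ± 0.207, with adjusted p between 0.115 and 0.165. In the fit of 11 libraries the median was 0.18 with an adjusted p of 2.23e-05 (adjusted p = 0.911 with an estimated correlation), and 1 member was higher over all genes and 5 adjusted over the list alone. Ifit1, Isg15, Usp18 and Bst2 did not turn there, with log2 changes of -0.06, -0.08, -0.01 and -0.02 (limma, adjusted p from 0.915 to 0.983). With the stricter filter the median was -0.13 (adjusted p 0.0169) and with a pseudocount of 5 it was -0.12 (adjusted p 0.00407). Without BPS replicate 3 the median was -0.31 with an adjusted p of 1.48e-05, and without BPS replicate 4 it was -0.11 with an adjusted p of 0.0137. Its adjusted p ranged from 1.48e-05 to 0.195 over 29 alternatives, either direction included.

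In that fit, the genes of smallest p encoded interferon-inducible GTPases. Tgtp1 was at 12.3 ± 2.74 FPKM in vehicle (n = 8) and 63.9 ± 19.3 FPKM in BPS replicates 1, 2 and 3 (n = 3), a log2 change of 2.28 ± 0.205 with an adjusted p of 0.00124. Gbp4 (1.89 ± 0.201), Iigp1 (1.75 ± 0.19) and Igtp (1.72 ± 0.177) had an adjusted p of 0.00159. With all 15 libraries the changes of these genes were 0.54, 0.41, 0.49 and 0.45, with adjusted p between 0.474 and 0.618. Tgtp1 lay below every vehicle library in 3 of the 4 BPS libraries left out. The neutrophil genes S100a8 (1.47 ± 0.249), S100a9 (1.36 ± 0.225) and Retnlg (1.35 ± 0.23), the immediate-early genes Ier2 (1.59 ± 0.199) and Junb (1.36 ± 0.199), the aryl hydrocarbon receptor gene Ahr (0.69 ± 0.122) and the acyl-CoA thioesterase gene Acot1 (2.05 ± 0.365) also passed. Apart from S100a8 and Acot1, these genes were named after their values were seen.

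**Figure D4:**
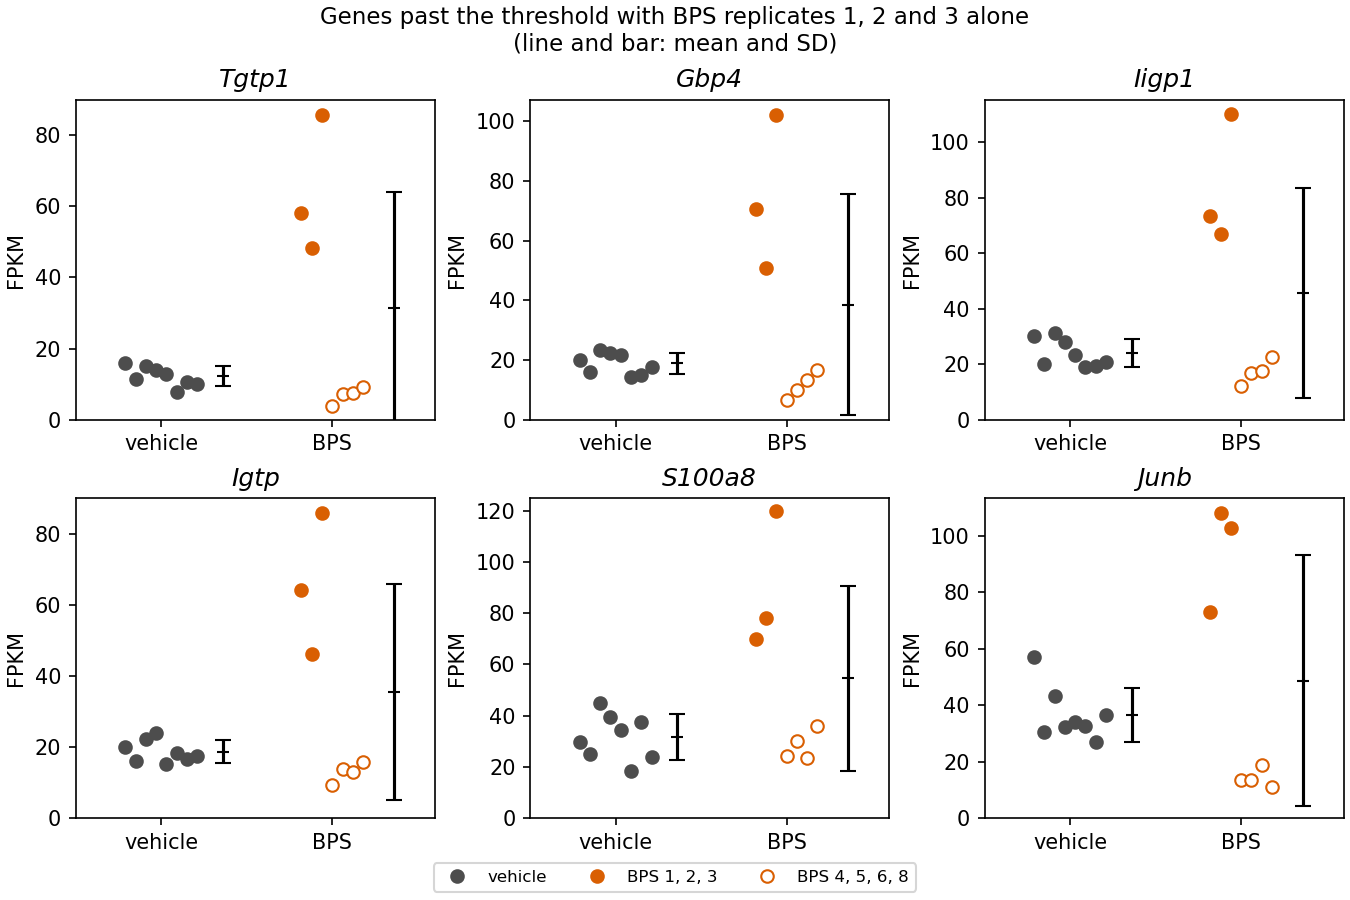
Points are FPKM of single libraries for 6 genes past the threshold in the fit without BPS replicates 4, 5, 6 and 8 (open points), with the mean and SD of each group over all its libraries. Filled BPS points lie above the vehicle points, with a mean of 63.9 FPKM against 12.3 in vehicle for Tgtp1.

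Markers of other cell types moved as follows. Skeletal muscle markers were lower in all 24 members, with a median of -2.05 and an adjusted p of 1.47e-06 (adjusted p = 0.724 with an estimated correlation). Myl1, Eno3, Neb and Pvalb had log2 changes of -1.87 ± 0.819, -1.75 ± 0.919, -1.65 ± 0.93 and -3.01 ± 1.7, with adjusted p between 0.194 and 0.294, and none passed by either adjustment. The muscle score varied within groups, from 2.15 to 10.5 in vehicle and from 0.982 to 8.10 in BPS (log2 FPKM), and its group difference of -2.10 had an exact permutation p of 0.171. Macrophage markers were higher in all 19 tested members, with a median of 0.40 and an adjusted p of 0.00359 (adjusted p = 0.724 with an estimated correlation). Trem2 (1.19 ± 0.375), Cd68 (0.96 ± 0.328), Lyz2 (0.66 ± 0.249) and Mpeg1 (0.57 ± 0.225) had adjusted p between 0.113 and 0.161, and none passed by either adjustment. Cd68 was at 10.2 ± 2.07 FPKM in vehicle, 10.2 ± 1.58 FPKM in BPS replicates 1, 2 and 3, and 24.2 to 46.4 FPKM in the 4 other BPS libraries, and without those the macrophage list was lower, with a median of -0.07 and an adjusted p of 0.0348 (adjusted p = 0.911 with an estimated correlation). With the muscle score as a covariate the skeletal muscle list had a median of 0.04 and an adjusted p of 0.528, and without vehicle replicates 2, 6 and 8 a median of -0.29 and an adjusted p of 0.206. With the Y-linked level as a covariate its median was -0.83 (adjusted p 0.019). Without the 4 BPS libraries its median was -1.59 with an adjusted p of 0.000977 (adjusted p = 0.911 with an estimated correlation). Over 29 alternatives adjusted p ranged from 8e-10 to 0.87 for skeletal muscle and from 0.000149 to 0.517 for macrophage markers.

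Erythrocyte markers were lower, with a median of -0.38 over 6 tested members and an adjusted p of 0.00359. The hemoglobin genes Hba-a2, Hbb-bt and Hba-a1 had log2 changes of -0.44 ± 0.215, -0.44 ± 0.226 and -0.31 ± 0.221 and did not pass by either adjustment, while 1 member of the list was lower over all genes and 1 adjusted over the list alone. Without BPS replicate 1 the median was -0.25 with an adjusted p of 0.0188, with the muscle score as a covariate it was -0.57 (adjusted p 1.02e-05), and without vehicle replicates 2, 6 and 8 it was -0.61 (adjusted p 2.76e-06). Nerve and Schwann cell markers had a median of -0.37 over 10 members and an adjusted p of 0.0065, with S100b, Gfra3 (-0.45 ± 0.151) and Sox10 (-0.27 ± 0.204) among its members. Smooth muscle and pericyte markers had a median of -0.33 over 13 members and an adjusted p of 0.0065, with Abcc9 (-0.49 ± 0.164), Rgs5 (-0.57 ± 0.259), Des (-1.38 ± 0.757) and Notch3 (-0.26 ± 0.159). Each of these 3 lists had an adjusted p = 0.724 with an estimated correlation, and no nerve or smooth muscle marker passed by either adjustment. The erythrocyte and nerve lists were also lower without the 4 libraries, with adjusted p of 0.000921 and 0.0166 (adjusted p = 0.911 with an estimated correlation), and the smooth muscle list had a median of 0.05 and an adjusted p of 0.596. With the muscle score as a covariate the median of the nerve list turned to 0.07 (adjusted p 0.346) and that of the smooth muscle list was -0.12 (adjusted p 0.0649). With the stricter filter the nerve list had a median of -0.47 and an adjusted p of 0.0515, and with a pseudocount of 5 one of -0.18 and an adjusted p of 0.00564. Without vehicle replicates 2, 6 and 8 the nerve median was 0.18 (adjusted p 0.91), and it was -0.20 and -0.22 without vehicle replicate 2 or 6 alone (adjusted p 0.0265 and 0.0255). The smooth muscle median was -0.19 without vehicle replicate 1 (adjusted p 0.0252), and -0.51, -0.55 and -0.50 without vehicle replicate 5, vehicle replicate 7 or BPS replicate 2 (adjusted p from 0.00146 to 0.00451). Over 29 alternatives adjusted p ranged from 2.63e-06 to 0.042 for erythrocyte, from 0.000473 to 0.91 for nerve and from 0.000454 to 0.596 for smooth muscle markers. No score of the 13 lists of other cell types differed after adjustment (exact permutation test, adjusted p from 0.317 to 0.852), and those of macrophages and erythrocytes had unadjusted p of 0.0448 and 0.0494.

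**Figure D5:**
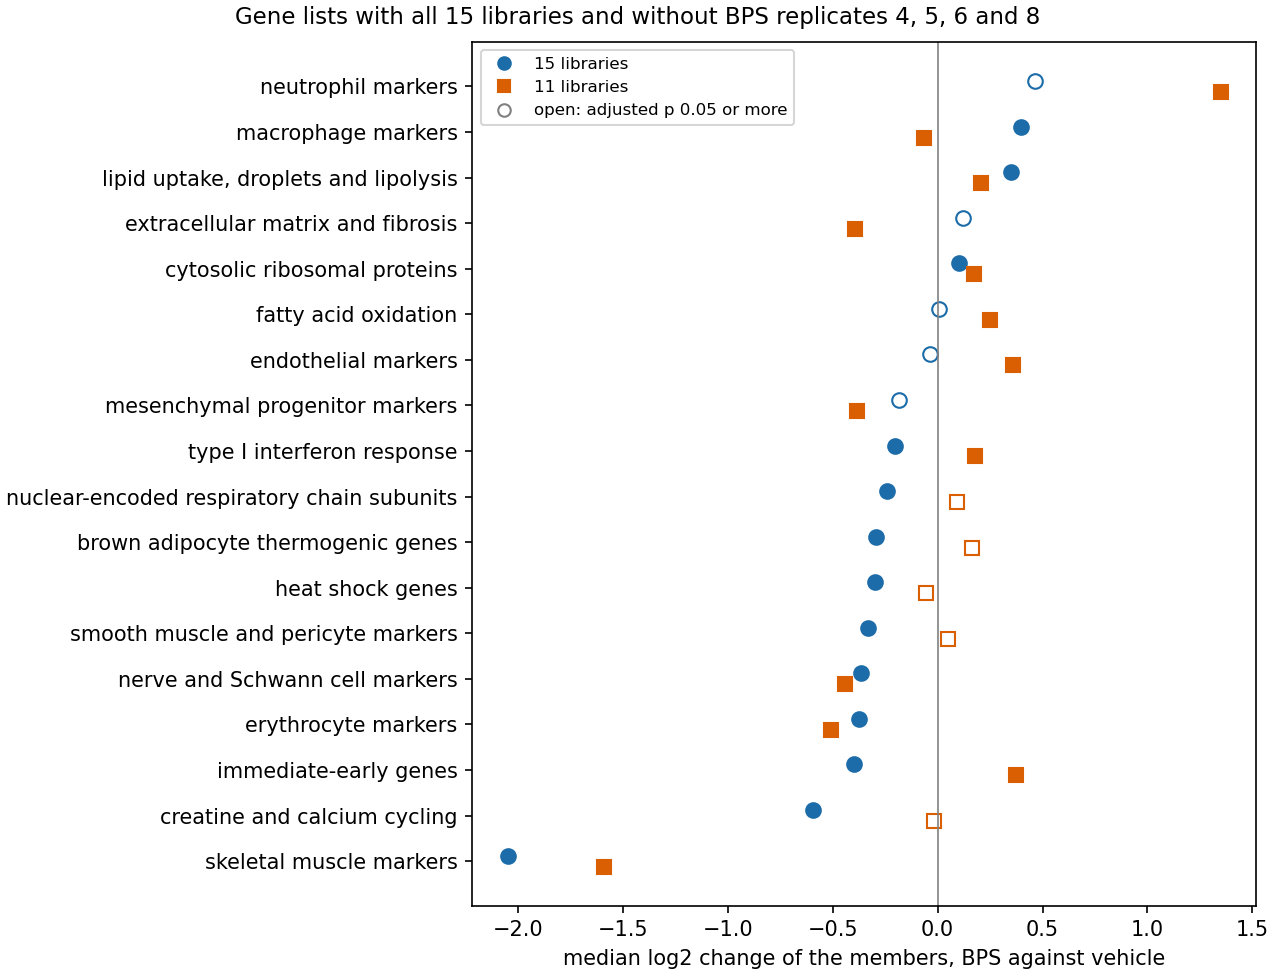
Each line gives the median log2 change of the members of a gene list that passed camera's test in either fit, with all 15 libraries (circles) and without BPS replicates 4, 5, 6 and 8 (squares), filled where the adjusted p is under 0.05 with a preset correlation. Immediate-early genes lie at -0.40 and 0.37, type I interferon genes at -0.20 and 0.18, and skeletal muscle markers at -2.05 and -1.59.

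The remaining lists did not pass with all libraries. Among metabolic lists, adjusted p was 0.0628 for the tricarboxylic acid cycle (median -0.10, Pdha1 -0.27 ± 0.154), 0.745 for fatty acid oxidation (Acot1 1.397 ± 0.331), 0.113 for lipogenesis (median -0.14, Fads1 0.68 ± 0.264), 0.942 for cholesterol synthesis (median 0.06, Cyp51 -0.31 ± 0.101), 0.277 for glucose uptake (median -0.03, Akt1 0.44 ± 0.108) and 0.45 for mitochondrial dynamics (median -0.02, Bnip3 0.54 ± 0.172). Among stress and turnover lists it was 0.446 for antioxidant genes (Slc7a11 0.48 ± 0.14), 0.315 for the unfolded protein response (Calr 0.46 ± 0.113), 0.113 for the proteasome (Psmc4 -0.12 ± 0.0678), 0.0507 for autophagy and lysosome genes (median 0.20, Ctsl 0.51 ± 0.127), 0.102 for the cell cycle (Birc5 -0.45 ± 0.139) and 0.718 for the circadian clock, with Bhlhe40 as the member of smallest p. The extracellular matrix list had an adjusted p of 0.942 (Tnc -1.10 ± 0.311). Medians were positive while camera's direction was lower for fatty acid oxidation (0.0078), extracellular matrix (0.12), circadian clock (0.07) and mast cell markers (0.16). None of these lists held a gene past the threshold over all genes. Adjusted over the list alone, 1 member was higher in each of the fatty acid oxidation, glucose uptake and autophagy lists, and 2 were higher and 1 lower in each of the unfolded protein response and circadian lists. Among cell type lists, adjusted p was 0.814 for T and natural killer cell (median -0.01, Il7r 0.39 ± 0.182), 0.315 for B and plasma cell (median -0.24 with 7 of 8 members negative, Cd37 0.35 ± 0.255), 0.958 for neutrophil, 0.915 for mast cell (Cma1 0.78 ± 0.332), 0.243 for endothelial (Cldn5 -0.93 ± 0.369) and 0.0706 for mesenchymal progenitor markers (Clec11a -0.25 ± 0.0936). Epithelial markers had too few tested members for camera, and their score had an exact permutation p of 0.462, or 0.6 after adjustment.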

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

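All tests of explanations in this part were chosen after the results were seen, except the count of other splits of the 15 libraries. A single library lay far from the rest of its group in 12 of 228 sets of values examined, where chance gives about 1 in 20. The values in parentheses are the gap to the nearest library divided by the range of the group, on log2(FPKM + 1). Vehicle replicate 1 was highest for Nr4a3 (0.561), Vdr (0.532), Atf3 (0.654) and Il6 (0.598). BPS replicate 4 was lowest for S100b (0.68), Cox7a1 (0.677), Cox7c (0.669), Cox5a (0.626), Atp5l (0.603), Ucp1 (0.614) and Cidea (0.578), and BPS replicate 3 was lowest for Adrb3 (0.659). Vehicle replicate 1 had 22.4 FPKM of Nr4a3, 2.46 of Vdr, 139 of Atf3 and 3.2 of Il6, where the nearest vehicle library had 7.87, 1.55, 48.6 and 0.78 FPKM. BPS replicate 4 had 5.19 FPKM of S100b, 311 of Cox7a1, 2191 of Cox7c, 771 of Cox5a, 2434 of Atp5l, 82.3 of Ucp1 and 320 of Cidea, where the nearest BPS library had 20.4, 1837, 4021, 1913, 3795, 578 and 1319 FPKM. For Adrb3, BPS replicate 3 had 45.4 and the nearest 90.3 FPKM.

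BPS replicates 4, 5, 6 and 8 had lower Y-linked transcripts than all other libraries. A response shared by BPS-exposed mice is argued against by the 3 BPS libraries inside the vehicle range, and an exchange of whole samples by the 3 libraries (BPS replicates 5, 6 and 8) that lay between 10% and 80% of the vehicle mean. A candidate explanation is RNA of a second source without Y-linked transcripts, present in unequal shares. If these libraries share such a source, they are not independent, and p-values with all libraries do not measure the spread between mice alone. Over 23 autosomal genes seen in BPS replicate 4 and near 0 in the 11 other libraries, the median level relative to BPS replicate 4 was 66.8%, 35.7% and 22.2% in BPS replicates 8, 5 and 6, where the loss of Y-linked transcripts gives 73.6%, 46.5% and 25.5%, a largest difference of 10.8 percentage points. Single genes varied widely around these medians, with quartiles of 40.9% to 80.4%, 17.8% to 46.2% and 16.3% to 31.1%. For BPS replicate 4 alone, at 0.437%, an exchange of the whole sample and a mixture made almost wholly of another source cannot be told apart, since both predict a level near 0.

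The 50 genes called over all 15 libraries were more than other splits gave. Of 100 splits, 1, the real one, reached that number, and the highest other gave 1 gene. That share is the smallest that 100 splits can give. It argues against a random division of the libraries as the source of the count. The 4 libraries are all in BPS, so the splits cannot tell an effect of BPS from what these 4 share. The 4 libraries as the whole cause are argued against for the 5 genes that passed without them. The fits share 11 libraries, and chance is not excluded for the smaller fit. All of the 5 but Xlr3b passed it narrowly, at an adjusted p of 0.0432 to 0.0434 (limma). For the other 45 the median change without them was 0.796 of that with them, but the genes were chosen partly by the values of BPS replicates 1 to 3, so a contribution of the 4 libraries cannot be told apart from an effect of BPS. For carry-over of skeletal muscle, the ratio of changes with and without the muscle score had a lower quartile of 0.885. The genes were chosen by the fit without that score, which favours a high ratio, so it does not decide on this explanation. That covariate took the median size of change from 0.697 to 0.623 and the median SE from 0.131 to 0.135, and took the calls from 50 to 2.

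The genes called with BPS replicates 1, 2 and 3 alone included the interferon-inducible GTPases. Of 100 splits of the 11 libraries, 2 gave at least the real 33 genes, the real one included. This division was itself chosen after the data were seen, so its rank cannot exclude chance. The highest other split gave 2042 genes and set vehicle replicates 2, 6 and 8 apart, those with the highest skeletal muscle scores. Whether its genes follow those scores was not tested. A response shared equally by all exposed mice and lowered by the second source was set against a response of some of them. Over the genes as a set these cannot be told apart. In BPS replicates 5 and 6 the medians lay below the level an equal response requires. Upper quartiles there did not all pass the bound of -0.3, which allows for the spread of the Y-linked level. In BPS replicate 8 the amount added by the second source is unknown. The GTPase genes Tgtp1, Gbp4, Iigp1 and Igtp lay below their vehicle means in BPS replicates 5 and 6, at 7.57, 13.41, 17.46 and 13.14 FPKM in the latter. The lowest of BPS replicates 1 to 3 had 48.36, 50.87, 67.05 and 46.29 FPKM, and BPS replicate 6 kept 74.5% of the Y-linked level. These GTPase genes were chosen by their values in BPS replicates 1 to 3, which favours such a gap. With each of BPS replicates 1 to 3 held out and 32 genes chosen with the others, the highest median log2 ratio to the level in the held-out library times the Y-linked level was -0.389 in BPS replicate 5 (upper quartiles from -0.527 to 0.224), -0.837 in BPS replicate 6 (upper quartiles from -0.703 to -0.135) and 0.631 in BPS replicate 8. A batch shared by replicates 1 to 3 of both groups is argued against as the whole cause. For this, 32 genes were chosen without vehicle replicates 1 to 3, 22 of them among the called ones. Vehicle replicates 1 to 3 differed from the other vehicle libraries by a median log2 of 0.205 (quartiles 0.0894 and 0.382), against 1.35 in BPS. Over the called genes, whose choice used these vehicle libraries, the median was 0.116. A smaller shared shift is not excluded, since the 32 genes were chosen for high values in BPS replicates 1 to 3. A batch of BPS replicates 1 to 3 alone was not tested.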

How the results depend on the processing

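The fits without several libraries and that with the Y-linked level were chosen after seeing the data. The cause of the differences was not tested, except where fewer genes or libraries were used. The alternative with a surrogate variable was not run, and the alternatives that need counts did not apply. Counts of higher and lower genes, 42 and 8 as reported, were 59 and 20 under median scaling, 8 and 1 without a filter, 24 and 5 with the stricter filter, and 15 and 2 with a pseudocount of 5. They were 1 and 1 with the muscle score, 0 and 0 with the Y-linked level or without vehicle replicates 2, 6 and 8 (limma; 970 and 1440 genes at an unadjusted p under 0.05), 32 and 1 without BPS replicates 4, 5, 6 and 8, and 29 and 2 when the muscle score was added to that fit. Each library left out in turn gave 0 to 61 higher and 1 to 27 lower genes. All 50 genes kept their sign in every setting that tested them, which their choice by a fit of the same libraries favours. The median ratio of their changes to the reported ones was 0.925 with the muscle score and 0.745 with the Y-linked level. It was 0.908 without vehicle replicates 2, 6 and 8. With the replicate block the counts were 34 and 4, and the ribosomal protein list had an adjusted p of 0.0721. The numbers do not pair the samples: deviations of same-numbered libraries correlated from -0.418 to 0.583, and 2 of the 7 BPS libraries correlated best with their own number. Counts of higher and lower lists, 3 and 10 as reported, were 5 and 10 without a filter, 0 and 0 with an estimated correlation, 7 and 6 without the 4 libraries, 6 and 7 with the Y-linked level, and 5 and 4 without the 4 libraries with the muscle score. Leaving out each library gave 2 to 4 and 10 to 13. No cell type score passed in the settings run for them: the median over members, standardized members, median scaling, paired differences by replicate number, without the 4 libraries, and each library left out. Values whose direction turned are log2 changes, medians for lists. Without the 4 libraries they were 0.163 for thermogenic genes, 0.0932 for respiratory subunits, 0.179 for interferon genes, -0.0674 for macrophage markers, 0.0493 for smooth muscle markers, 0.374 for immediate-early genes, 0.0205 for Ndufa5, 0.0184 for Alpl, -0.0593 for Lyz2, -0.0356 for Mpeg1, -0.0745 for Cma1, 0.0493 for Rgs5, 0.0109 for Notch3, 0.795 for Ucp1, 0.501 for Cidea, -0.102 for Cdkn1a, -0.168 for Lep and -0.0155 for Esr1. With the Y-linked level they were 0.13 for thermogenic genes, 0.0968 for respiratory subunits, 0.0737 for interferon genes, 0.00386 for macrophage markers, 0.107 for smooth muscle markers, 0.36 for immediate-early genes, 0.0802 for Cox7a1, 0.0155 for Ndufa5, 0.106 for Rgs5, 0.037 for Notch3, 0.918 for Ucp1, 0.161 for Dio2 and 0.542 for Cidea, where the macrophage list turned in camera's direction alone. With the 4 libraries left out and the muscle score added they were 0.152 for interferon genes, -0.103 for macrophage markers, 0.201 for smooth muscle markers, 0.517 for immediate-early genes, 0.0024 for Ndufa5, -0.0169 for Cd68, -0.0928 for Lyz2, -0.0775 for Mpeg1, -0.0365 for Cma1, 0.0711 for Rgs5, 0.0312 for Notch3, 0.01997 for Sox10, 0.0465 for Klf2, 0.383 for Ucp1, 0.187 for Cidea, -0.00482 for Prdm16 and -0.0821 for Lep. They were 0.0698 for Atp2a2, 0.0681 for Sox10 and -0.0344 for Prdm16 without vehicle replicates 2, 6 and 8, -0.0278 for Prdm16 with the muscle score and 0.129 for Ucp1 with the replicate block. Medians turned while the direction of camera did not for skeletal muscle (0.0412) and nerve markers (0.0695) with the muscle score, heat shock genes with the Y-linked level (0.00353), nerve markers without vehicle replicates 2, 6 and 8 (0.177) and skeletal muscle markers without the 4 libraries with the muscle score (0.0554). List calls also ended without the 4 libraries with the muscle score for thermogenic (-0.00372), respiratory (-0.00411), lipid (0.0917), creatine (-0.0178), nerve (-0.0895) and heat shock genes (-0.035), and with the Y-linked level for the creatine list (-0.00224). With each library left out, Ucp1 ranged from -0.29 to 0.47, Cidea from -0.45 to 0.14 and Adrb3 from -0.26 to 0.0132. Of 2823 values of named genes under alternatives, 2457 kept direction and side of the threshold, 307 lost the call, 16 gained it and 43 turned in direction. Depth is unknown, so its limit on low genes was not assessed.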

Other observations

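All tests in this part were chosen after the data were seen, except the count of other splits. Without BPS replicates 4, 5, 6 and 8, further gene groups moved. Extracellular matrix genes were lower, with a median log2 change of -0.39 and an adjusted p of 5.07e-07 (camera; adjusted p = 0.911 with an estimated correlation), and 2 members were lower adjusted over the list alone. Fatty acid oxidation genes were higher, with a median of 0.25 and an adjusted p of 0.00101, as were endothelial markers (0.36, adjusted p 0.00139), each with an adjusted p = 0.911 with an estimated correlation. Adjusted over the list alone, 1 fatty acid oxidation gene and no endothelial marker was higher (limma). Neutrophil markers were higher with a median of 1.35 over 5 tested members and an adjusted p of 0.000209 (adjusted p = 0.58 with an estimated correlation), and 3 of them were higher both over all genes and adjusted over the list alone. The neutrophil score over all 13 members differed by 0.44, with an exact permutation p of 0.00606, the smallest that 3 against 8 libraries can give, and 0.0788 after adjustment. Mesenchymal progenitor markers were lower (-0.38, adjusted p 0.00458; adjusted p = 0.911 with an estimated correlation), with 1 member higher and 2 lower adjusted over the list alone. Among these 11 libraries their score was highest in vehicle replicates 2, 6 and 8, at 3.86, 3.84 and 3.69. Those libraries also have the highest skeletal muscle scores. It was 2.91 to 3.59 in the other vehicle libraries, against 3.12 to 3.30 in BPS replicates 1 to 3.

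The number of lists called does not exclude chance. Of 100 splits of the 15 libraries, 58 gave at least the 13 lists of the real split, and the highest other gave 21.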
